A study of Mus musculus with 2 samples.

How the data were processed

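Total RNA from adrenal glands of male B6CASTF1/J mice (36 days) was purified with a column kit for animal tissue, and directional libraries depleted of ribosomal RNA were made from 300 ng each with ERCC spike-in RNA, per the labels. The 2 libraries form 1 group and are named by the biological replicate number of their labels. The biosample descriptions name a different animal for each library, while both library descriptions name the same animal, so the labels conflict on this point.

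Each library came with a gene table and 2 transcript tables on mm10 and GENCODE M21. The gene table and the first transcript table hold expected counts that the authors derived from a transcriptome alignment, in the column layout of RSEM. The TPM values were deposited as scaled by the authors to a fixed sum over all entries, spike-ins and tRNA included. The percentage of a gene's TPM in each transcript was also computed by the authors before the files were deposited; transcript shares were recomputed here from TPM. The second transcript file holds estimated counts and TPM that the authors derived from the reads, in the column layout of kallisto. Program names and versions are not given in the sources used here. All 55536 gene identifiers matched the annotation; 26248 tRNA, 96 ERCC and 1 phiX entries name no gene and were left out of the gene tests.

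The gene tables summed to 35813366 and 30628771 expected counts in replicates 1 and 2, and the second transcript files to 35293226 and 28100411. Spike-ins took 0.843% and 1.50% of the gene tables. With 49 spike-ins at 10 or more counts in both libraries, the SD of their log2 count ratio was 0.19. Intervals are exact 95% limits on the ratio of 2 counts, and they and the floor of 3 counts cover counting error only, since reads without molecular identifiers are not independent molecules. A gene at 0 counts in 1 library was set to the floor of 3 counts, and its fold is given as a lower bound.

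Levels are the deposited TPM, as mean and SD over the 2 libraries. Agreement was measured across genes by Pearson's r and Spearman's rho of log2(TPM + 1), by the SD of the log2 ratio, and by the common biological coefficient of variation of edgeR 4.0.16 from an intercept-only design (R 4.3.3). Genes with a mean CPM of at least 1 were compared between the libraries by a two-sided exact binomial test on rounded counts, with library sizes scaled by TMM (factors 1.02 and 0.982) and 0.5 added to counts for log2 ratios. Genes passed with a Benjamini-Hochberg adjusted p under 0.05 and a log2 ratio of at least 1 in size, over 14780 genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

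For each of 33 gene lists the median log2 ratio of tested members was ranked among 10000 random lists of the same size, drawn from the 200 genes nearest in mean expression to each member (seed 1). A list with at least 3 tested members was set apart when its median lay outside the central 95%. The tests, the lists and the rule for named genes were fixed before the data were examined. That rule takes the 15 nuclear protein-coding genes with the highest mean TPM and all steroidogenesis and chromaffin cell genes. It also takes up to 4 members of each other list by mean TPM, up to 4 by size of the log2 ratio where the list stood apart, and 10 named protein-coding genes in each direction with a mean CPM of at least 5.

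The procedure was tested on simulated data of 14780 genes with 200 changed. With counting error alone, 100% of genes changed by a log2 ratio of 1.5 or 2 were found and 1 unchanged gene was called. With a biological coefficient of variation of 0.2 added, 86.9% and 99.0% were found and 356 unchanged genes were called. Of 100 unchanged lists of 15 genes, 2 and 4 were set apart in the 2 simulations.

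Alternatives were DESeq2 1.42.0 size factors and dispersion, total counts and spike-in counts as scaling, no filter, a mean CPM of at least 5, the second transcript file, nuclear protein-coding genes only, a 1.5-fold threshold, the edgeR exact test at a fixed coefficient of 0.1, other pseudocounts and TPM columns, and each replicate left out for levels and ratios. Of the settings, 3 were chosen after seeing the data. The first left out genes at least 32-fold higher in replicate 2. The second took nuclear protein-coding genes of unique symbol with counts whole within 0.01 as having no shared reads. The third rescaled the second file over nuclear protein-coding genes. Some members of the lists count in list totals but are not reported here by gene.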

Results

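Total RNA was sequenced from the adrenal glands of male B6CASTF1/J mice, the F1 hybrid of the C57BL/6J and CAST/EiJ strains, at 36 days of age. The series holds 1 group of 2 biological replicates, so the design gives the expression profile of this tissue and the spread between its 2 libraries, and no contrast between conditions. Each library was made from 300 ng of RNA with spike-in RNA added. The gene tables summed to 35813366 expected counts in replicate 1 and 30628771 in replicate 2, of which 22693400 and 17847778 fell on nuclear protein-coding genes. Of 22015 such genes, 11526 reached 1 TPM (transcript abundance scaled to the same sum in each library) in both libraries. Gene identifiers follow GENCODE M21 and positions are on mm10.

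The adrenal cortex program led the profile. Ranked by mean TPM, the top nuclear protein-coding genes were Star, which brings cholesterol into the mitochondrion, at 4187 ± 1971 TPM (mean ± SD, n = 2, as for the levels that follow), and Hsd3b1, a 3-beta-hydroxysteroid dehydrogenase, at 2591 ± 798 TPM. They were followed by Akr1b7 at 1930 ± 908, Cyp11a1, the side-chain cleavage enzyme, at 1899 ± 817, and Eef1a1, a translation elongation factor, at 1728 ± 531. Cyp21a1, the steroid 21-hydroxylase, reached 1428 ± 545, Scd1, a fatty acid desaturase, 1312 ± 53.7, Cyp11b1, the 11-beta-hydroxylase of corticosterone synthesis, 1162 ± 385, and Fabp4, a fatty acid carrier of fat and endothelial cells, 1060 ± 31.2. Scarb1, the HDL receptor, was at 1030 ± 530, Fdx1 at 893 ± 499, Fasn, the fatty acid synthase, at 893 ± 151 and Fth1 at 873 ± 163. The 2 remaining genes of the top 15 were digestive enzymes of the pancreas found in replicate 2, Ctrb1 at 0.11 and 2563 TPM and Cela2a at 0.06 and 1792 TPM in replicates 1 and 2. The 7SL RNA genes Rn7s1 and Rn7s2, which carry identical values, took 32.5% of the TPM of replicate 1 and 48.9% of replicate 2. Nuclear protein-coding genes took 31.0% and 23.2%. An SD of deposited TPM therefore mixes this difference in scale with the spread of the gene itself. With TPM rescaled over nuclear protein-coding genes alone, Star was at 14995 ± 4210 and Scd1 at 4958 ± 1206.

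All 21 members of the steroidogenesis list reached 1 TPM in both libraries, and their TPM summed to 21588 in replicate 1 and 11619 in replicate 2. Star (ENSMUSG00000031574.8, chromosome 8, 25806555 to 25815982, plus strand) held 426264 and 227313 expected counts. Cyp11a1 (ENSMUSG00000032323.13, chromosome 9, 58006411 to 58027023) held 177119 and 103959, and Hsd3b1 (ENSMUSG00000027871.16, chromosome 3, 98852194 to 98859794) held 181127 and 127993. The electron donors of the mitochondrial and microsomal P450 enzymes followed, with Fdxr at 356 ± 134 TPM and Por at 78.0 ± 28.2. The ACTH receptor Mc2r was at 78.5 ± 27.2 TPM, its partner Mrap at 145 ± 103, the cholesterol esterifying enzyme Soat1 at 450 and 308 TPM in the 2 libraries, the hormone-sensitive lipase Lipe at 98.8 ± 6.44 and Cyb5a at 90.4 ± 27.0. The transcription factor Nr5a1 was at 106 ± 75.9 TPM and its partner Nr0b1 at 1.55 ± 0.601. Cyp17a1, the 17-alpha-hydroxylase that adult mouse adrenals are known to lack, was at 3.17 and 1.05 TPM. With TPM rescaled over nuclear protein-coding genes alone the list summed to 69528 and 49994, and the summed TPM of the steroidogenesis list was 33388 in mean in the second transcript file, against 16603 here. Cyp21a1, Hsd3b6 and Cyp11b2 carry counts that are not whole numbers, so part of their reads was split with other transcripts.

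**Figure D1:**
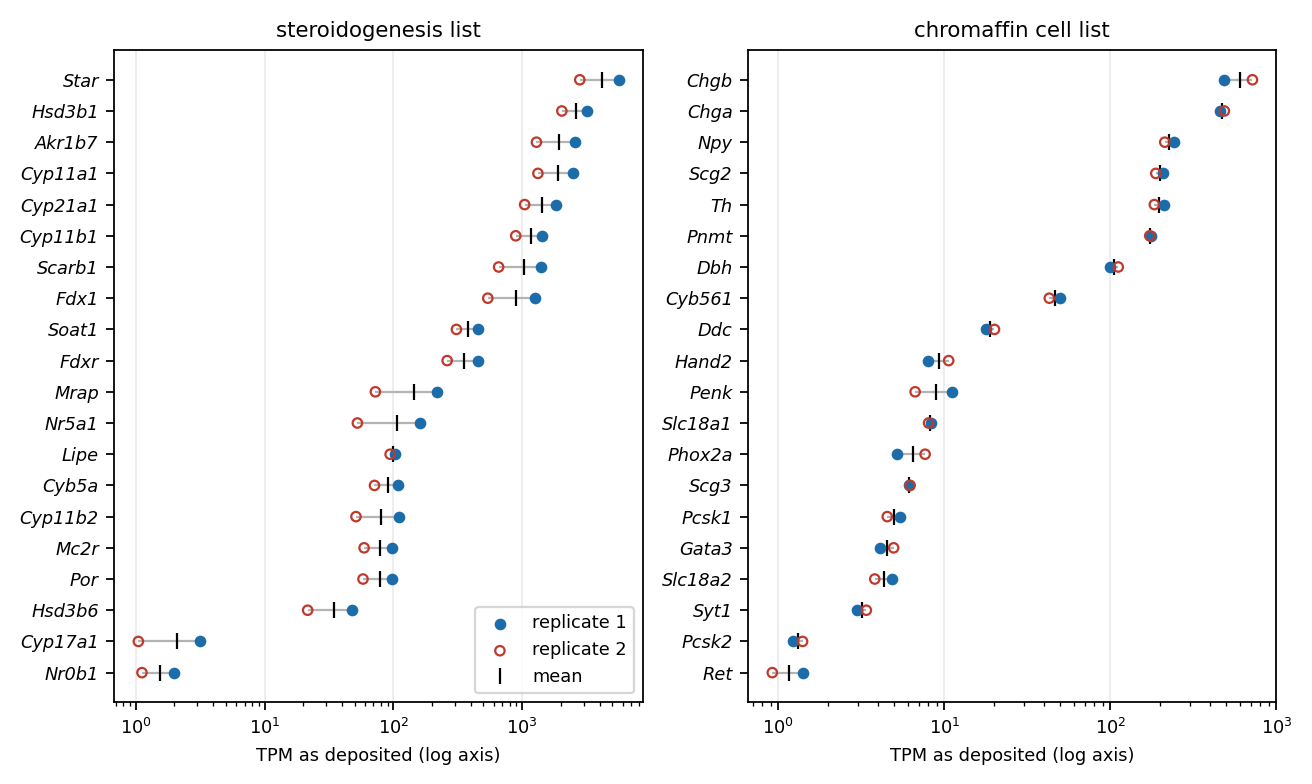
TPM as deposited (log axis) of 20 genes of the steroidogenesis list and 20 genes of the chromaffin cell list. Filled points are replicate 1, open points replicate 2, ticks their mean and grey lines the range; Star had the highest mean of the first list (4187 TPM) and Chgb of the second (601 TPM).

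The adrenal medulla was present in both libraries, with 20 of 21 chromaffin cell genes at 1 TPM or more in each. Chgb and Chga, proteins of the secretory granule, had the highest levels at 601 ± 165 and 471 ± 20.1 TPM. Of the enzymes of catecholamine synthesis, Th (ENSMUSG00000000214.11, chromosome 7, 142892752 to 142931128) was at 197 ± 18.6, Ddc at 17.9 and 20.1 TPM in the 2 libraries, Dbh at 106 ± 8.22 and Pnmt (ENSMUSG00000038216.7, chromosome 11, 98386450 to 98388181), which makes adrenaline from noradrenaline, at 174 ± 1.97 TPM. With TPM rescaled over nuclear protein-coding genes alone, Pnmt was at 565 and 743 in replicates 1 and 2, or 654 ± 126. In deposited TPM, Npy was at 226 ± 19.5, Scg2 at 198 ± 14.1, Cyb561 at 46.4 ± 4.94, Penk at 8.91 ± 3.16, Slc18a1 at 8.19 ± 0.205 and Slc18a2 at 4.33 ± 0.735 TPM. The transcription factors Hand2, Phox2a and Gata3 lay between 4.51 and 9.30 TPM in mean, and Scg3, Pcsk1, Syt1, Pcsk2 and Ret between 1.17 and 6.16.

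Within each library, Cyp11b1 stood 13.1 and 17.4 times above Cyp11b2, the aldosterone synthase of the outer cortex (mean 15.2 ± 3.03, n = 2), and 10.1 ± 1.34 times in the second transcript file. Hsd3b1 stood 79.8 ± 19.9 times above Hsd3b6, its relative in the outer cortex. Pnmt was at 0.886 ± 0.0736 of Th. The summed steroidogenesis list was 10.8 times the summed chromaffin cell list in replicate 1 and 5.29 times in replicate 2, a mean of 8.02 ± 3.87. Akr1c18, the 20-alpha-hydroxysteroid dehydrogenase of the transient inner X-zone, was at 0.000867 ± 0.000352 of Cyp11b1, or 0.00132 ± 0.000236 in the second file. With 60 and 23 expected counts, Akr1c18 was at the low end of what this depth could measure.

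Among cell type lists, the 10 zona glomerulosa genes reached 1 TPM in both libraries, led by Agtr1a, the angiotensin receptor, at 131 ± 35.1 TPM, and Dab2 at 112 ± 27.2. The 6 zona fasciculata genes summed to 4944 ± 2133 TPM and included Abcb1b at 598 ± 180. The X-zone list held Thrb at 8.55 ± 0.778 and Akr1c18 at 1.08 ± 0.742 TPM, and Pik3c2g lay under 1 TPM in both. Fat markers were abundant, with Cfd at 352 ± 136, Ucp1, the uncoupling protein of brown fat, at 229 ± 103 and Plin1 at 158 ± 1.03 TPM. Hemoglobin genes were led by Hba-a1 at 830 ± 437 and Hbb-bs at 727 ± 367 TPM. Of stroma, Col3a1 was at 94.3 ± 44.5 and Dcn at 57.8 ± 20.4; of endothelium, Plvap at 50.1 ± 15.9 and Egfl7 at 40.7 ± 3.22; of pericytes and smooth muscle, Tagln at 37.5 ± 24.5; of macrophages, Lyz2 at 42.7 ± 18.1 and C1qa at 18.8 ± 4.52. Schwann and sustentacular cell genes were low, the highest being S100b at 5.38 and 3.61 TPM in the 2 libraries. Lymphocyte, kidney and skeletal muscle lists summed to 0.980 ± 0.0707, 1.38 ± 0.396 and 1.10 ± 0.127 TPM.

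Other gene groups gave the following levels. Srd5a2, a steroid 5-alpha-reductase (ENSMUSG00000038541.8, chromosome 17, 74016955 to 74047916), was by far the highest of the steroid-metabolising enzymes at 726 ± 244 TPM, against 37.8 ± 3.43 for Hsd11b1, and Cyp19a1 had 0 counts in both. Of hormone receptors, Insr was at 45.9 ± 12.7, Ghr at 41.5 ± 14.6 and Prlr at 22.6 ± 10.3 TPM. Imprinted genes were led by the noncoding Meg3 at 270 ± 38.8 and Rian at 181 ± 39.6 and the coding Dlk1 at 181 ± 27.8 TPM. The 13 mitochondrially encoded protein genes summed to 50091 ± 5308 TPM, and 80 of the 83 cytosolic ribosomal protein genes reached 1 TPM in both libraries, with Rpl41 at 761 ± 146. Antioxidant genes were led by Gpx4 at 358 ± 49.6 and Sod1 at 321 ± 73.7 TPM. The noncoding Rn7sk stood at 34848 ± 8284 and Malat1 at 4794 ± 776 TPM. In the second transcript file Rn7sk was at 1.56 and 1.26 TPM in replicates 1 and 2, against 4003 and 4276 for Malat1. The level of Rn7sk thus depends on the file. All 4 Y-linked genes were detected, Ddx3y at 25.5 ± 11.2 TPM, while Xist, the X-inactivation RNA of female cells, was at 0.03 and 0.02.

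The 2 libraries ranked genes alike and still differed well beyond counting error. Across 55536 genes, many of them without counts, Pearson's r of log2(TPM + 1) was 0.980 and Spearman's rho was 0.928. Over the 14780 tested genes they were 0.948 and 0.955. Genes are not independent replicates, and these values describe these libraries only. Over 14780 genes with a mean CPM of at least 1, the SD of the log2 ratio was 0.99 and its interquartile range 0.49. The chi-square of the counts was 160 as a mean per gene, where counting error alone gives about 1. That mean is weighted toward abundant genes and those with large ratios, so it does not describe a typical gene. The SD was 0.58 without the 89 genes at least 32-fold higher in replicate 2. The agreement of the 2 libraries, biological coefficient of variation, was 0.318 as the common edgeR value and 0.238 without those genes. The median of the per-gene DESeq2 estimates, an unlike measure, was 0.0974. A total of 1015 genes (6.87%) passed both thresholds of the exact binomial test, 758 higher in replicate 2 and 257 higher in replicate 1. The test sets 1 library against 1, so it compares these libraries and not conditions. Scaled by the spike-ins instead, 237 were higher in replicate 2 and 5279 in replicate 1, with every log2 ratio shifted by -0.89. Replicate 1 held 118 gene counts per spike-in count and replicate 2 held 65.7.

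**Figure D2:**
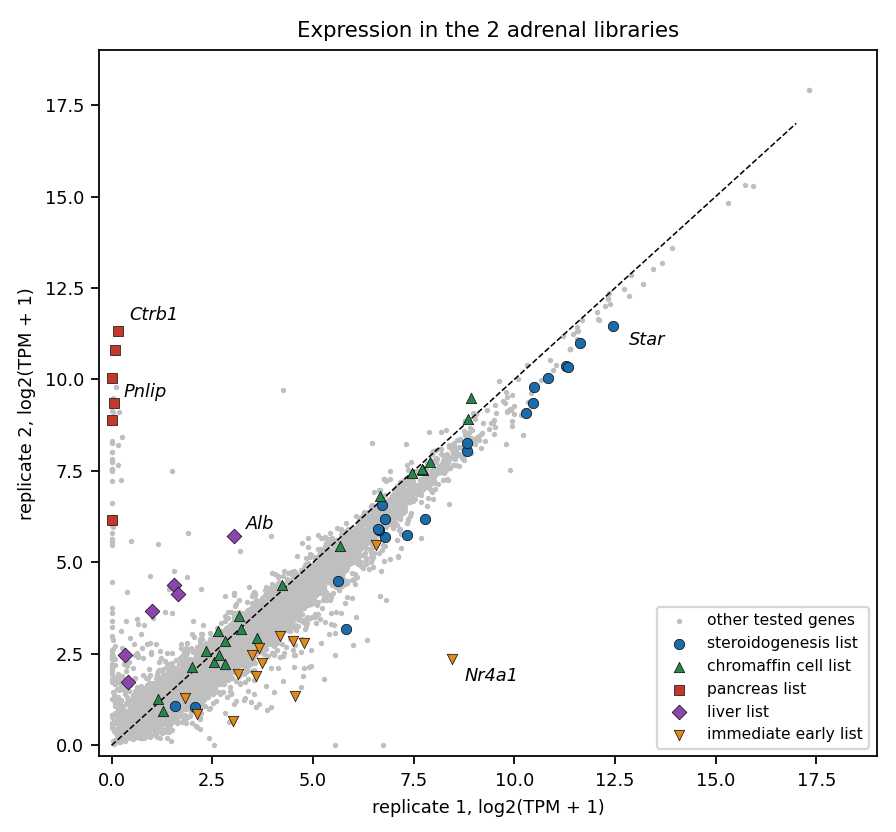
Expression of 14780 genes in replicate 1 (x axis) and replicate 2 (y axis), each as log2(TPM + 1), with 5 gene lists marked and the line of equality dashed. The 6 pancreas genes lie near 0 TPM in replicate 1 and between 71.0 and 2563 TPM in replicate 2; Nr4a1 lies at 350 and 4.09 TPM.

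Replicate 2 carried RNA of pancreas genes that was almost missing from replicate 1. All 6 genes of the pancreas list passed, with 6 expected counts in all in replicate 1 and 222557 in replicate 2, and a median log2 ratio of 14.58, or 14.14 with the 3 genes at 0 counts set at their bound. Pnlip, the pancreatic lipase (ENSMUSG00000046008.8, chromosome 19, 58652498 to 58681788), had 0 and 53335 counts and was at least 21714-fold higher. Ctrb1, a chymotrypsinogen (ENSMUSG00000031957.6, chromosome 8, 111686519 to 111691010), had 3 and 77528 counts, a ratio of 31563 with a 95% exact interval of 10800 to 153055. Cpa1 (0 and 27197 counts) was at least 11072-fold higher, and the insulin gene Ins2 (0 and 1007 counts) at least 410-fold. The 10 largest ratios among named protein-coding genes also held Dmbt1, Try10 and the amylases Amy2a1, Amy2a2, Amy2a3 and Amy2a4. Amy2a2, Amy2a3 and Amy2a4 had identical values (26042 counts each in replicate 2), as near-identical copies that share reads, so their split is uncertain. All 6 liver genes passed as well: albumin, Alb (ENSMUSG00000029368.10, chromosome 5, 90460897 to 90476602), stood at 7.24 and 51.4 TPM and was 9.54-fold higher in replicate 2 (95% exact interval 8.68 to 10.5), and Apoa1 was 13.8-fold higher (10.7 to 18.1). The 78 nuclear protein-coding genes at least 32-fold higher in replicate 2 took 3.51% of its coding counts and 0.00436% of those of replicate 1.

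Immediate early genes were the most shifted list in the other direction, with a median log2 ratio of -1.34, below all 10000 random lists of the same size and expression. All 14 tested members were higher in replicate 1, of which 10 passed and 4 did not. Nr4a1, an orphan nuclear receptor induced by ACTH (ENSMUSG00000023034.7, chromosome 15, 101254269 to 101274795), had 28730 and 335 counts and was 70.2-fold higher in replicate 1 (95% exact interval 63.0 to 78.4). Nr4a2 was 15.3-fold higher (12.9 to 18.4), Fosb 9.99-fold (7.69 to 13.2), Nr4a3 3.60-fold (3.38 to 3.84) and Junb 2.62-fold (2.34 to 2.93). Among named protein-coding genes, the 10 largest ratios toward replicate 1 also held Sik1, a salt-inducible kinase, at 12.8-fold (11.5 to 14.3), Plk3 at 10.6-fold, Nfil3 at 9.32-fold, Susd3 at 8.03-fold, 2010109I03Rik at 7.83-fold and Gem at 7.56-fold. The heat shock list had 7 of 8 members higher in replicate 1, with 4 passing and 4 not (median log2 ratio -1.20, below all random lists). Those passing were Hspa1b at 8.24-fold, Hspa1a at 7.14-fold, Dnajb1 at 2.94-fold and Bag3 at 2.86-fold. Hspa1a and Hspa1b are near-identical copies that share reads.

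Genes of cholesterol supply and steroid synthesis also lay higher in replicate 1, as did the erythroid, stroma and macrophage markers (median log2 ratios -0.83, -0.36 and -0.30). Chromaffin cell genes, 18 of 21 higher in replicate 2, and adipocyte genes, 6 of 9 higher there with a median of 0.37, went the other way. Both medians are negative under spike-in scaling. Of 23 tested genes of cholesterol synthesis and uptake, 5 passed and 18 did not (median log2 ratio -0.77, below all random lists). Among those passing, Sqle, the squalene epoxidase, was 2.12-fold higher in replicate 1 (95% exact interval 1.97 to 2.28). Msmo1, at 2.01-fold, and Mvd, at 2.01-fold, lay at the threshold, and Msmo1 no longer passed with a mean CPM of at least 5 (log2 ratio -0.96). Of the 21 steroidogenesis genes 4 passed, all higher in replicate 1, and 17 did not (median log2 ratio -0.48, below all random lists). Those passing included Nr5a1 at 2.27-fold (2.20 to 2.34), Mrap at 2.26-fold (2.16 to 2.37) and Cyp17a1 at 2.21-fold (1.68 to 2.95). Star was 1.54-fold and Hsd3b1 1.16-fold higher in replicate 1, below the 2-fold threshold. The zona fasciculata list (1 of 6 passing, Mrap, median -0.45) lay at percentile 1.14 of its random lists. All its genes but Abcb1b are also in the steroidogenesis list, so this is not a separate result. The zona glomerulosa list, with none of 10 passing and a median of -0.19, lay at percentile 11.9. Of its genes 8 were lower and 2 higher in replicate 2. Cyp11b2 (1.60-fold) and Hsd3b6 (1.62-fold), shared with the steroidogenesis list, were higher in replicate 1, against 1.20-fold for Cyp11b1.

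In all, 20 of the 29 lists with at least 3 tested genes lay outside the central 95% of their random lists, 13 lower and 7 higher in replicate 2. Besides pancreas (percentile 99.99) and liver (median log2 ratio 3.53, above all random lists), the lists higher in replicate 2 were the chromaffin cell, interferon response, adipocyte, mitochondrially encoded protein and circadian clock lists, and their medians of 0.40, 0.65, 0.37, 0.31 and 0.20 all turn negative under spike-in scaling. None of the 21 chromaffin cell genes passed, with Chgb closest at 1.99-fold (95% exact interval 1.97 to 2.01), and none of the 12 interferon response genes, with Ifit3 at 1.99-fold (1.66 to 2.39). Of 9 adipocyte genes, Elovl3 (8.04-fold, 6.57 to 9.92) and Ucp1 (2.59-fold, 2.53 to 2.66) passed, and Cidea stood at 2.00-fold (1.92 to 2.07), just under the threshold. The adipocyte list was not uniform, with 3 of the 9 lower in replicate 2, none of them passing. Of the 13 mitochondrially encoded genes only mt-Co2 passed, at 4.76-fold, and in the second transcript file its log2 ratio was 0.13. The circadian clock genes went both ways: Per1 was 4.61-fold (4.29 to 4.96), Per2 2.95-fold (2.78 to 3.13) and Npas2 2.31-fold higher in replicate 1, and Per3 2.40-fold (2.17 to 2.65) higher in replicate 2, with 11 not passing.

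**Figure D3:**
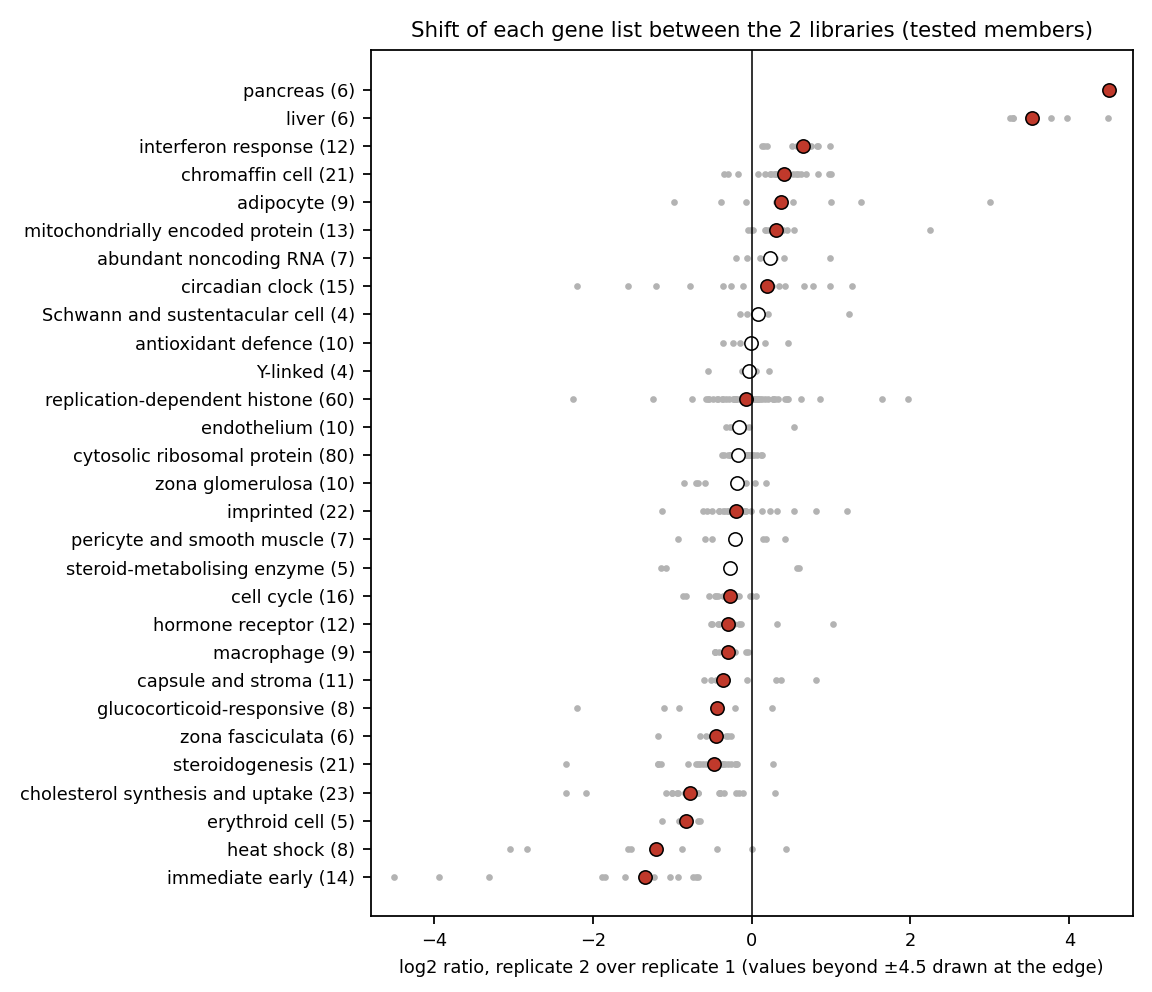
Log2 ratio (replicate 2 over replicate 1, x axis) of 29 gene lists, with the number of tested members in brackets. Grey points are genes, large points list medians, red where the median lies outside the central 95% of 10000 random lists and white otherwise; the immediate early median (-1.34) is the lowest, and medians between 0 and 0.65 turn negative under spike-in scaling.

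The other lists lower in replicate 2 were erythroid cell (median -0.83, percentile 0.05), glucocorticoid-responsive (-0.44, 0.04), capsule and stroma (-0.36, 0.15), macrophage (-0.30, 0.665), hormone receptor (-0.30, 0.59), cell cycle (-0.28, 0.04), imprinted (-0.20, 1.96) and replication-dependent histone (-0.07, 0.17). Of 5 erythroid genes 1 passed, Hba-a2 at 2.19-fold, which shares reads with Hba-a1 and did not pass in the second transcript file (log2 ratio -0.68). Per1 and Tsc22d3 (2.15-fold) passed of 8 glucocorticoid-responsive genes, and Fkbp5 stood at 1.88-fold. None of the 9 macrophage, 11 capsule and stroma or 16 cell cycle genes passed. All 9 macrophage genes were lower in replicate 2, while 3 capsule and stroma and 2 cell cycle genes were higher there. Of the 12 hormone receptors Nr3c2 passed, 2.04-fold higher in replicate 2, and of 22 imprinted genes H19 passed toward replicate 1 (2.19-fold) and Airn toward replicate 2 (2.31-fold). Of 60 histone genes 2 passed in each direction, Hist1h2ap and Hist1h2ai toward replicate 1 and Hist2h2aa1 and Hist1h2ao toward replicate 2. Histone copies share reads, and none of these 4 calls held in the second transcript file: the log2 ratio there was -0.19 for Hist1h2ap, 0.31 for Hist1h2ai and 0.12 for Hist2h2aa1, and Hist1h2ao was at 0 TPM in both libraries. The imprinted list lay inside the central range with a mean CPM of at least 5, at percentile 2.97.

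Lists inside the central range were endothelium (median -0.16, percentile 25.005), pericyte and smooth muscle (-0.21, 7.23), Schwann and sustentacular cell (0.08, 24.4), cytosolic ribosomal protein (-0.17, 14.3), antioxidant defence (-0.01, 91.0), abundant noncoding RNA (0.23, 93.1), steroid-metabolising enzyme (-0.27, 5.02) and Y-linked (-0.03, 61.4). The Schwann cell gene Erbb3 passed, at 2.34-fold higher in replicate 2, and Cyp17a1 and Akr1c18 of the steroid-metabolising enzymes passed toward replicate 1. Akr1c18, at 2.14-fold (95% exact interval 1.30 to 3.62), did not pass in the second transcript file (log2 ratio -0.58). That enzyme list rests on 5 tested genes and moved to percentile 98.0 with a mean CPM of at least 5 and to 0.14 with no filter. The X-zone and kidney lists had 2 tested genes each, with medians of -0.46 and -0.23, and no lymphocyte or skeletal muscle gene was tested. Scaled by the spike-ins, Ucp1, Per3, Erbb3, Airn, Nr3c2 and Hist1h2ao were among the genes that no longer passed. Ins2, Mvd, Cyp19a1, Xist, Rn7s1 and Rn7s2 were named after their values were seen. Adjusted over the list alone, each list gave the same counts of passing genes as over all genes tested.

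The 2 transcript files of each library ranked genes alike and transcripts less so. Spearman's rho between them was 0.735 and 0.732 over 141767 transcripts in replicates 1 and 2, and 0.980 and 0.979 over 21938 nuclear protein-coding genes after summing TPM per gene. Over transcripts at 1 TPM or more in either file, rho was 0.454 and 0.456. Of the 42 steroidogenesis and chromaffin cell genes, 8 have 1 annotated transcript, which leads by construction. The other 34 each had the same leading transcript in both libraries, and 31 of them had it in both files as well. It held over 50% of the gene's TPM in both libraries for 32 of the 34 in the first file, with 52.3% for Star in replicate 1. For Th it held 100% in replicate 1 in the first file and 69.5% in the second. The 3 genes whose leading transcript differed between files were Hsd3b1 (Hsd3b1-201 in the first file, Hsd3b1-202 in the second), Nr5a1 (Nr5a1-201 and Nr5a1-202) and Ddc (Ddc-202 and Ddc-210), named after their values were seen.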

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

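This signal was looked at only after its values were seen. The tRNA entries of the gene tables, which no comparison used, held 8.06 expected counts in replicate 1 and 7.81 in replicate 2. These are sums over 26248 entries, of which 5 and 4 were above 0. The floor of 3 counts is a bound for 1 entry, so it cannot say whether these sums exceed noise. No biological explanation was tested.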

How the results depend on the processing

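The tests without genes at least 32-fold higher in replicate 2, without shared reads, and on the second file rescaled over nuclear protein-coding genes were chosen after the data were seen; the others were planned. Except where stated, the cause of a change was not tested. Of the 1015 passing genes (758 higher in replicate 2, 257 in replicate 1), the counts became 5516 (237 and 5279) with spike-in scaling, which shifts every log2 ratio by -0.89. They became 2038 (1613 and 425) with no filter, 348 (195 and 153) with a mean CPM of at least 5, and 2454 (1694 and 760) at a 1.5-fold threshold. Over 11169 nuclear protein-coding genes of unique symbol and whole counts, taken as having no shared reads, 573 passed, 378 of them higher in replicate 2. With all nuclear protein-coding genes tested, 865 passed, 633 of them higher in replicate 2. Shifts of 29 lists kept their side of the threshold in the second transcript file. The 20 lists that stood apart also kept direction, which was not checked for the others. DESeq2, total-count and spike-in scaling move every log2 ratio alike, so they cannot change a percentile and say nothing about its stability. The imprinted list lay at percentile 2.97 with a mean CPM of at least 5. The steroid-metabolising enzyme list lay at 0.14 with no filter (8 genes), 0.06 among nuclear protein-coding genes (6 genes) and 98.0 with a mean CPM of at least 5 (3 genes). The log2 ratio of Hist1h2ai was 0.31 in the second file. Over genes at 1 TPM or more in both libraries, the agreement of the 2 libraries, Spearman rho, was 0.966, and the agreement of the 2 libraries, SD of the log2 ratio, 0.43. The agreement of the 2 libraries, biological coefficient of variation, was 0.0974 by DESeq2, as a median of per-gene estimates. The common edgeR value was 0.238 without genes at least 32-fold higher in replicate 2. The summed TPM of the steroidogenesis list was 33388 in the second file, 59761 over nuclear protein-coding genes and 56795 with both; the summed TPM of the chromaffin cell list was 4522, 7958 and 7711. In the second file the ratio of Cyp11b1 to Cyp11b2 was 10.1 and the ratio of Akr1c18 to Cyp11b1 was 0.00132. Spearman rho of the 2 transcript files, replicate 1, was 0.454 at 1 TPM or more in either file, and Spearman rho of the 2 transcript files, replicate 2, was 0.456. Of 208 log2 ratios of named genes, 6 no longer passed and 78 newly passed with spike-in scaling. In the second file, 6 of 202 kept their direction and no longer passed, and 1 newly passed. A further 1, Hist1h2ai, reversed direction and no longer passed. Of 220 levels of named genes, 188 moved by more than their SD in the second file, 182 of them upward. With TPM over nuclear protein-coding genes, all 204 levels that could be rescaled moved upward by more than their SD. Leaving out a replicate moved no level of 33 lists by more than its SD, which 2 libraries make certain. With 1 library against 1, depth does not limit the calls for abundant genes, but the spread between animals cannot be measured apart from that between libraries.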

Other observations

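Tests of separately prepared samples, pooled reads, dilution, scaling and handling, and the genes of the next 2 paragraphs, were chosen only after the result was seen.

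Replicate 2 also carried RNA of islet and acinar regulators. Islet hormone genes had 0 counts in replicate 1: Ins1 was at least 191-fold higher in replicate 2 (469 counts), Iapp at least 42.7-fold (105 counts) and the glucagon gene Gcg at least 33.0-fold (81 counts). Of acinar transcription factors, Rbpjl was at least 199-fold higher (489 counts) and Ptf1a at least 18.3-fold (45 counts). Liver genes outside the fixed list included Apob at 15.9-fold (95% exact interval 13.5 to 18.8) and Cyp3a11 at 20.7-fold (15.4 to 28.5).

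In replicate 1, Crem, a transcription factor gene induced by cAMP, was 3.77-fold higher (3.52 to 4.04) and Alas1, the first enzyme of heme synthesis, 3.89-fold (3.79 to 3.99). The 7SL genes Rn7s1 and Rn7s2 were each 2.02-fold higher in replicate 2 (log2 ratio 1.02), which does not pass under the spike-in shift of -0.89, and took 0.000180% and 0.00168% of TPM in the second transcript file. Genes of up to 350 nt had a median count of 0 in that file relative to the gene table, and genes above 2000 nt had 1.11 times theirs in both libraries.

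The spread between the 2 libraries bears on the conflict in the labels. The same RNA of 1 animal in both was predicted to give a coefficient of variation under 0.05. Simulated counting error with 200 truly changed genes gave 0.1004. The same RNA would hold no changed genes, so that simulation cannot say whether the bound was set well. The agreement of the 2 libraries, biological coefficient of variation, was 0.318 as the common edgeR value, and 0.238 without genes at least 32-fold higher in replicate 2. Both lie above 0.05. The 0.0974 by DESeq2 is a median of per-gene estimates and an unlike measure. The coefficient thus depends on the estimator and the genes entered, and is weak evidence alone. At most 1% of genes with a mean CPM of at least 10 were predicted to lie 1.5-fold apart, and 744 of 9048 (8.22%) did, and Nr4a1 had 28730 and 335 counts, which argues against the same RNA in both. Separately prepared samples of 1 animal stay open, since the immediate early median of -1.34 does not decide this without collection times, and different animals stay open too, untested.

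The pancreas genes in replicate 2 may come from pancreatic tissue in the sample. In a second pancreas list, chosen before its values were seen, 7 of 7 genes were at least 10-fold higher there, with Cela1 (18.2 and 844 TPM) and Cpb1 (1.84 and 180 TPM) the highest and 2 of them at 1 TPM or more in replicate 1; none is in another list. In a second liver list 9 of 10 genes were at least 2-fold higher, Hp being the exception at 1.36-fold, which is consistent with liver tissue carried along; 5 of the 10 reached 1 TPM in replicate 1. Reads of a pancreas library in the same pool stay open, since the 3.51% of coding counts in genes at least 32-fold higher could come from either source. No biological explanation within the adrenal gland was tested.

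Immediate early genes were higher in replicate 1 by a median of -1.34 (replicate 2 over 1). Dilution of replicate 2 by the genes at least 32-fold higher there would give about -0.0515, a minimum, since other RNA of those organs was not counted. A scaling moves all genes alike, while the list lay -1.35 from the median of all tested genes and below all random lists. These values argue against scaling, and against dilution of that size, as the whole cause. Acute stimulation through cAMP before replicate 1 was collected is a candidate explanation. A second list of 10 cAMP-induced genes, chosen before its values were seen, had a median of -0.81, below all random lists. In it 8 genes were lower in replicate 2 and 2 of them passed, Csrnp1 (3.19-fold) and Klf4 (2.19-fold). Ppargc1a (log2 ratio 0.58) and Pde4b (0.12) were higher in replicate 2 without passing. The spike-in shift makes both negative, but it moves every gene alike and takes the median of all tested genes to -0.88. No bound was set for handling, so this list cannot tell cAMP from handling. Handling or time to freezing stays open, since the heat shock median of -1.20 could follow from either, and other differences between the samples were not tested.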
